A study of Brassica napus with 12 samples.

How the data were processed

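RNA was sequenced from apical meristems of rapeseed (Brassica napus), an allotetraploid whose A and C subgenomes carry many genes as near-identical pairs called homoeologs. The 12 libraries fall into 4 groups of 3: the line ZS11, labelled wild type; SX3, labelled a natural mutant; and 2 classes of plants from a second backcross between them, Zlike and Slike, named for the parental plant type they show. Groups were taken from the sample titles. The labels do not say whether a library came from 1 plant or from several, so p-values measure only the spread between these libraries, which may be technical.

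The authors deposited a table with a read count per gene for each of the 12 libraries, in whole numbers and without normalization, per the file headers. The same table gives FPKM values that the authors computed; recomputed from the deposited count, the deposited gene length and the library's total count, FPKM differed from the deposited values by no more than rounding error (largest relative deviation 8.4e-15), so FPKM added nothing to the count and was not tested. The tools fastp, HISAT2 and featureCounts are named in the submitters' processing notes, without versions. Their settings, the use of strand in counting, the treatment of reads that match several places, and the genome build are not given in the sources used here. Reads from homoeologs and other near-identical copies, from overlapping genes and from antisense partners may therefore have been split between genes, and every value for a single copy is uncertain to that extent. The gene IDs end in ZS, which may point to a genome of ZS11. In that case SX3 reads that differ from it could be lost, which would lower counts in SX3 and in SX3 segments of backcross plants. This was not tested and also limits the scale from ZS11 to SX3 used below. The table lists 100919 genes with coordinates, 96921 of them on 19 chromosomes named A01 to C09 and 3998 on unplaced scaffolds. Coordinates are those of the deposited table. Gene names were taken from the best protein match that the table gives. Such a match exists for 69773 genes, and for 57046 it is to a protein of the mustard family; a name of this kind identifies the gene family and need not identify the exact Arabidopsis counterpart. The authors also deposited 2 tables of their own comparisons, whose file names give FPKM, fold and adjusted p limits and name DESeq; only their direction words were used. Lists of gene IDs on the second sheets of those tables were not used here. A reference table of another annotation of the species shared no usable IDs with the deposited table and was not used here.

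Total counts ranged from 13445924 to 17778731 per library. A gene with 0 counts in a library is compatible with up to 3 counts at this depth, a floor of 0.169 to 0.223 CPM depending on the library; floors cover counting error only. Pairs of libraries of the same group differed by more than sampling noise (chi-square per gene of 1.35 to 1.47). This cannot tell separate plants from repeated preparations of the same material. Each library was entered as a replicate of its group. No library batch is given by the labels.

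Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as factor, libraries were scaled by TMM, and differences were tested by the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) with Benjamini-Hochberg adjustment over all genes kept. SX3 against ZS11 and Slike against Zlike were each fitted on their own 6 libraries. The difference between these comparisons, (Slike − Zlike) − (SX3 − ZS11), and the secondary comparisons of Zlike with ZS11 and of Slike with SX3 were fitted on all 12 libraries. A gene was called at an adjusted p under 0.05, and the number with an absolute log2 fold change of 1 or more is given beside it. Log2 fold changes are positive where the mutant type (SX3 or Slike) was higher. Levels are TMM-scaled CPM values, given as mean ± SD over 3 libraries. Standard errors were computed from the fold change and its quasi-likelihood statistic. Where a group had 0 counts in all 3 libraries, the fold is given as a lower bound against a floor of 3 counts per library, and where it held 1 to 3 counts, only the levels are given.

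The gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The 19 lists hold 1621 genes and were built from Arabidopsis genes by symbol, plus a keyword list of subtilases, the protease family that the series title points to. Lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 19 lists of a comparison. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move, on balance, one way. The genes named per main comparison were the 5 higher and 5 lower annotated genes with the smallest p among non-overlapping, at least 2-fold calls with a mean of 1 CPM or more; up to 2 called members per list with the smallest p; and, whatever their test gave, the most abundant copy of LFY, AP1, TFL1, FT, SOC1, FLC, FUL, SVP, WUS, CLV3 and STM. Across both comparisons the rule adds the 5 higher and 5 lower genes called in both with the smallest larger p, and the 5 genes with the smallest p in the most enriched window of Slike against Zlike. Called genes without a protein name (5814 in SX3 against ZS11 and 2010 in Slike against Zlike) were counted and not named. Windows of 100 consecutive tested genes were tested for an excess of called genes by a one-sided Fisher exact test with adjustment over windows, and chromosomes by a two-sided Fisher exact test.

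Alternatives were DESeq2 size factors (edgeR's RLE), upper-quartile scaling, no filter, a mean of 1 CPM or more, the Wald test of DESeq2 1.42.0, limma-voom, 1 fit of all 12 libraries, the replicate number as a block, each library left out in turn, windows of 50 and 200 genes, and calls limited to 2-fold changes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. In simulated counts for SX3 against ZS11 (50035 genes), the test recovered 46% of genes changed 1.25-fold, 67.3% at 1.5-fold, 90% at 2-fold and 92% at 4-fold, and 15 of 208 calls (7.21%) were false. For Slike against Zlike (49526 genes) these shares were 50%, 68%, 96% and 100%, with 14 of 216 calls (6.48%) false; both false shares lie above the nominal 5%. A planted gene list was found by camera in both simulations with 0 of the other lists called. Genes were drawn independently at a common dispersion and few were changed. The simulations therefore do not test the preset correlation or data in which most genes differ. The window scan, tested on simulated calls for 49366 placed genes of Slike against Zlike, found a planted window with 60% called genes in 20 of 20 runs, with 0 false windows.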

Results

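Apical meristems were profiled at the stage when the inflorescence primordium gives way to the first floral primordia, in rapeseed plants that differ in inflorescence and plant architecture. ZS11 (wild type), SX3 (natural mutant) and the backcross classes Zlike and Slike were represented by 3 libraries each. Total counts per library lay between 14608125 and 17778731 in ZS11, 13645330 and 17033511 in SX3, 13710697 and 15463623 in Zlike, and 13445924 and 14596920 in Slike. Libraries of a group resembled each other closely. The common coefficient of variation beyond counting noise was 2.70% in the comparison of the parents and 3.05% in Slike against Zlike. Whether this small spread lies between plants or is technical is not known from the labels. Across genes, log2 CPM of ZS11 correlated with that of SX3 at a median r of 0.785, and Zlike with Slike at 0.961, against 0.987 or more within groups; genes are not independent replicates.

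The first comparison asked how the meristem of the mutant SX3 differs from that of ZS11. Genes that specify flowers were far more abundant in SX3. AP1 on A07 (BnaA07G0307000ZS), a regulator of floral meristem identity, reached 20.9 ± 0.392 CPM (SD, n = 3) in SX3 against 2.33 ± 0.403 in ZS11, and FT on C06 (BnaC06G0323800ZS), the mobile flowering signal, 9.13 ± 0.528 against 0.685 ± 0.268. FLC on A02 (BnaA02G0035100ZS), a repressor of flowering, lay at 3.3 ± 0.468 CPM in SX3 against 38.5 ± 0.328 in ZS11. Genes of the photosynthetic apparatus and the clock gene LHY were lower in SX3. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 34681 of 50035 genes differed, 16733 of them higher and 17948 lower in SX3, and 13146 differed at least 2-fold (5231 higher, 7915 lower). Which direction held more called genes depended on the scaling: with upper-quartile scaling 18425 were higher and 16576 lower. If a ZS11 genome was used, loss of SX3 reads cannot be told apart here from lower expression in SX3.

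Floral meristem identity genes rose in SX3: 34 of 40 measured members were called higher and 2 lower, with a median log2 change of 2.5 (camera adjusted p = 6.17e-09, and adjusted p = 0.0179 with an estimated correlation). Adjusted over the list alone the counts were also 34 and 2. SEP2 on A01 (BnaA01G0416700ZS) was at 19.9 ± 2.1 CPM in SX3 and at 0 in all 3 ZS11 libraries, at least 106-fold higher. SEP1 on C03 (BnaC03G0075900ZS) rose 43.2-fold (log2 5.43 ± 0.18 SE, edgeR adjusted p = 1.57e-60). Both encode SEPALLATA proteins, MADS-box partners of the floral organ regulators. SEP2 starts at 36969127 of A01, and genes of other functions in that region also rose in SX3. RPS3A (from 35744630) rose by log2 6.07 and HDA19 (from 35793572) by 4.21. For SEP2 a change of the whole region cannot be told apart from a floral one. Of the floral organ identity genes, 15 of 21 were called higher and 2 lower, over the list alone likewise, with a median of 3.72 (camera adjusted p = 0.00028, but adjusted p = 0.151 with an estimated correlation). PI on C03 (BnaC03G0100100ZS) and AP3 on C08 (BnaC08G0343800ZS), which specify petals and stamens, rose by log2 5.25 ± 0.21 and 5.56 ± 0.24 (SE). Of the genes named LFY by their best protein match, the one with the highest counts lies on an unplaced scaffold. It was at 0.107 CPM in SX3 and at 0 in ZS11 and was too low to be tested. LFY copies matched to another protein name would be missed.

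Single regulators of flowering time and of the meristem went different ways. AP1 rose by log2 3.17 ± 0.13 (SE, edgeR adjusted p = 1.11e-50) and FT by 3.70 ± 0.21 (6.29e-36), while FLC fell by 3.56 ± 0.10 (2.73e-68). SVP, a further MADS-box repressor of flowering, rose by 0.68 ± 0.03 at its most abundant copy on A09 (BnaA09G0591400ZS) and by 2.30 ± 0.06 at a copy on A04 (BnaA04G0147200ZS). STM, which keeps meristem cells undifferentiated, fell by 0.55 ± 0.03 on C09 (BnaC09G0172400ZS) and by 1.27 ± 0.04 on A09 (BnaA09G0156700ZS). WUS on C09 (BnaC09G0117600ZS), a stem cell regulator, rose from 0.646 ± 0.181 to 1.38 ± 0.217 CPM (edgeR adjusted p = 0.00328). FUL on A03 (BnaA03G0404700ZS) fell by 0.38 ± 0.07. SOC1 on A03 (BnaA03G0221300ZS) fell by 0.11 ± 0.04 (edgeR adjusted p = 0.00929), a call that was lost with upper-quartile scaling (adjusted p = 0.252), with DESeq2 (0.050) and without ZS11 replicate 3 (0.0717). TFL1 on A03 (BnaA03G0012400ZS), the antagonist of floral identity, was at 44.8 ± 2.45 CPM in SX3 and 46.8 ± 3.89 in ZS11 (adjusted p = 0.301), and without ZS11 replicate 2 its log2 change of -0.13 passed the test (0.0337). CLV3 on A04 (BnaA04G0177000ZS), the stem cell peptide, was at 0.589 ± 0.209 and 0.610 ± 0.202 CPM (adjusted p = 0.964).

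**Figure D1:**
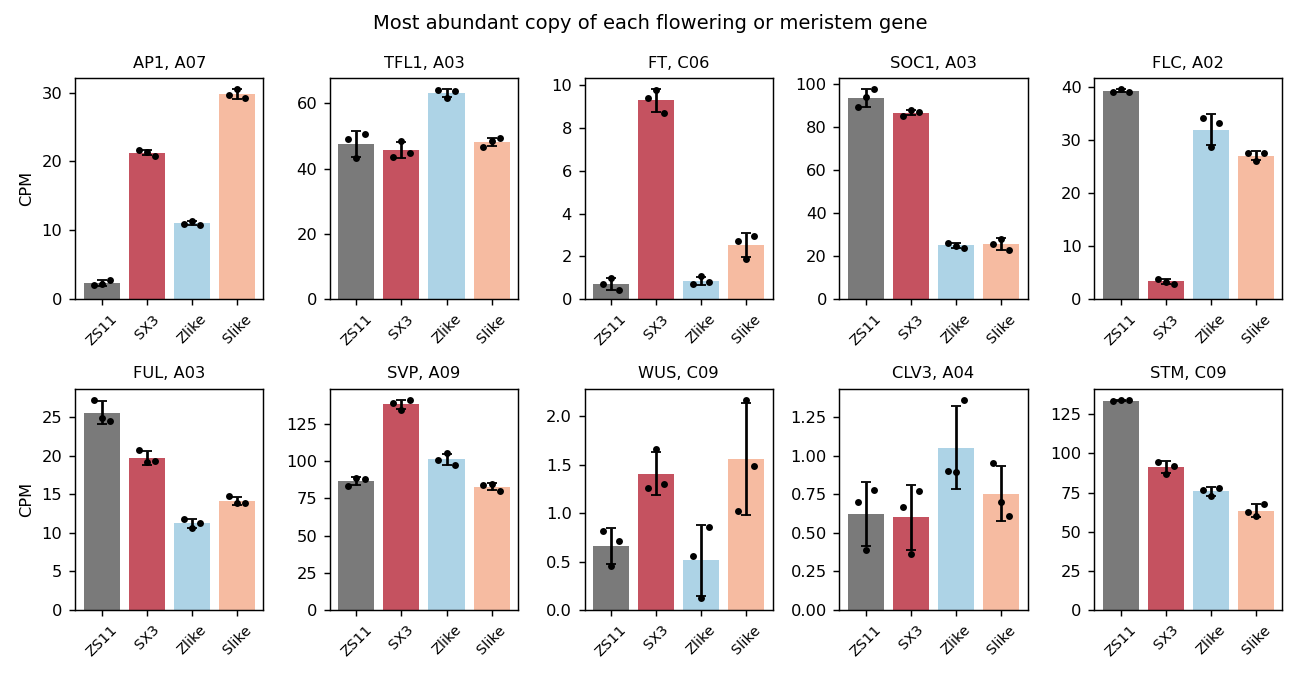
CPM of the most abundant copy of 10 flowering and meristem genes in the 4 groups, scaled over all 12 libraries; bars are group means, error bars are SD over 3 libraries and points are single libraries. AP1 lies at 21.3 CPM in SX3 and 29.8 in Slike against 2.37 in ZS11 and 11.0 in Zlike, while FLC lies at 3.36 CPM in SX3 and between 27 and 39.2 in the other groups.

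The list of flowering repressors as a whole was not called by camera, with 13 of 36 members higher and 10 lower (adjusted p = 0.651). Nor was flowering promotion, with 14 of 51 higher and 26 lower (camera adjusted p = 0.526, over the list alone 15 and 26). In the promotion list AGL24 on C01 (BnaC01G0180300ZS) and SPL9 on A05 (BnaA05G0029400ZS), both promoters of flowering, fell by 1.63 ± 0.08 and 1.05 ± 0.06.

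Photosynthesis genes fell in SX3: 43 of 60 were called lower and 11 higher, over the list alone likewise, with a median log2 change of -0.82 (camera adjusted p = 3.77e-08, and adjusted p = 0.0179 with an estimated correlation). The light-harvesting gene LHCB1.3 on A04 (BnaA04G0221200ZS) fell from 800 ± 9.00 to 90.2 ± 3.11 CPM and LHCB1.1 on A03 (BnaA03G0165600ZS) from 270 ± 5.48 to 10.7 ± 2.69 CPM. This list was meant as a marker of green tissue, so its fall may reflect a different amount of tissue other than the meristem proper. Light or time of day at sampling may also act on these genes. These readings were not tested and cannot be told apart here. Among the other tissue markers, 29 of 63 vascular and secondary wall genes were higher and 18 lower (adjusted p = 0.327; over the list alone 30 and 18), with APL on C06 (BnaC06G0361200ZS), a phloem regulator, lower by log2 -1.84. Only 6 of 37 anther and tapetum genes were measured, 4 higher and 2 lower (0.53), and organ polarity genes were higher in 33 of 63 and lower in 14 (0.111). In the polarity list FIL on C04 (BnaC04G0603400ZS), a YABBY gene of young organs, rose by 1.3 ± 0.05, and ARF4 on C02 (BnaC02G0118700ZS), between 0 and 9 Mb, was at 0 in SX3, at least 61.3-fold lower than 12.5 ± 0.702 CPM in ZS11.

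Among hormone lists, cytokinin and auxin were called by camera. Cytokinin genes were higher in 38 of 72 and lower in 12 (median 0.56, camera adjusted p = 0.00834) and auxin genes higher in 48 of 92 and lower in 15 (median 0.35, 0.0125; over the list alone 47 and 15). For both, the adjusted p = 0.151 with an estimated correlation. The cytokinin members with the smallest p, LOG8 and CKX7, both lie between 0 and 9 Mb of C02, a stretch where 558 of 619 genes were at least 4-fold lower in SX3: LOG8 on C02 (BnaC02G0049300ZS), an activator of cytokinin, fell from 48.9 ± 3.03 to 0.501 ± 0.20 CPM, and CKX7 on C02 (BnaC02G0107100ZS), which degrades it, from 16.9 ± 1.5 to 0.0243 CPM. In the auxin list GH3.6 on A03 (BnaA03G0125700ZS), an auxin-conjugating enzyme, rose by 3.1 ± 0.11 and the efflux carrier PIN3 on A07 (BnaA07G0322100ZS) fell by 2.21 ± 0.10. Gibberellin genes were higher in 22 of 39 and lower in 11 (adjusted p = 0.112); copies of GASA4 moved apart, from 125 ± 3.07 to 518 ± 2.48 CPM on A02 (BnaA02G0058500ZS) and from 98.6 ± 2.31 to 0.453 ± 0.162 on C02 (BnaC02G0067600ZS), in the same C02 stretch.

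Clock genes changed in 50 of 53 cases, 20 higher and 30 lower, with a median log2 change of -0.85. Camera did not call the list against all other genes (adjusted p = 0.225), while fry called it (adjusted p = 8.17e-07). LHY, a morning-phased clock regulator, fell from 244 ± 3.71 to 1.14 ± 0.24 CPM on A10 (BnaA10G0008600ZS) and from 165 ± 4.75 to 1.59 ± 0.263 on C05 (BnaC05G0010100ZS). Sampling of the groups at different times of day was not tested and cannot be told apart here from an effect of the genotype. Subtilases were higher in 13 of 48 and lower in 24 (0.0738); SBT3.3 on A03 (BnaA03G0461400ZS) fell by 4.77 ± 0.04 and SBT2.5 on A03 (BnaA03G0514500ZS) by 2.33 ± 0.05. Glucosinolate genes were higher in 17 of 48 and lower in 28 (0.112; over the list alone 18 and 28), with MYB34, a regulator of indole glucosinolates, lower by log2 -3.01 on C07 (BnaC07G0376700ZS) and -2.67 on C06 (BnaC06G0407900ZS). Shoot meristem maintenance genes were higher in 18 of 68 and lower in 31 (0.401), with the receptor kinase gene RPK2 on A01 (BnaA01G0417100ZS) at 22.4 ± 1.16 CPM against 0.0402 ± 0.035. RPK2 lies close to SEP2 on A01, so the same limit holds for it. Organ boundary and branching genes were higher in 15 of 40 and lower in 15 (0.828; over the list alone 16 and 15), with the strigolactone genes D14 on C05 (BnaC05G0554700ZS) and D27 on A09 (BnaA09G0135300ZS) lower, D14 by log2 -1.89 and D27 from 7.04 ± 0.813 to 0.0673 CPM. Cell division genes were higher in 42 of 83 and lower in 20 (0.112; over the list alone 43 and 20), stress genes higher in 8 of 27 and lower in 9 (0.90), and defence genes higher in 16 of 41 and lower in 16 (0.828). In these lists the cyclin gene CYCB1;2 (BnaC02G0023000ZS), like CYCA1;1 between 0 and 9 Mb of C02, was at 0 in SX3, at least 279-fold lower than 56.8 ± 2.55 CPM in ZS11, CYCA1;1 on C02 (BnaC02G0079000ZS) was at 0.0243 against 26.4 ± 2.33 CPM, and SID2 on C01 (BnaC01G0474900ZS), a salicylate synthesis gene, was at least 55.0-fold lower. The heat shock gene HSP101 fell by 3.22 ± 0.15 on A07 (BnaA07G0344900ZS) and 4.16 ± 0.24 on C06 (BnaC06G0406500ZS). Median and mean differed in sign for cell division, stress, defence and flowering repression. Fry gave an adjusted p between 5.37e-07 and 0.0206 over the 19 lists.

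Among the individual genes with the smallest p, the ribosomal protein gene RPS2A (BnaC03G0241200ZS, C03 14720662 to 14721806) was at 341 ± 3.90 CPM in SX3 and at 0.019 ± 0.0329 in ZS11. RPS3A on A01 (BnaA01G0401000ZS) was at 300 ± 3.21 against 4.45 ± 0.281 CPM. The histone gene HIS2B (BnaA10G0161600ZS, A10 19592672 to 19593097) rose 72.7-fold, GAPC on A01 (BnaA01G0404200ZS) 17.3-fold and the ribosomal protein gene ATL5 on C07 (BnaC07G0091600ZS) 8.88-fold. In the other direction, the methionine synthase gene MS1 on C02 (BnaC02G0084700ZS), between 0 and 9 Mb, went from 575 ± 9.76 to 0.381 ± 0.116 CPM, the tubulin gene TUBA4 on C02 (BnaC02G0500000ZS) from 382 ± 7.42 to 0.0431 ± 0.0378, the aquaporin gene TIP1-1 on A04 (BnaA04G0236300ZS) from 984 ± 15.0 to 20.9 ± 1.94, and PER22, a peroxidase gene on C03 (BnaC03G0216600ZS), from 779 ± 6.94 to 43.3 ± 2.12. EMS1 copies, in the anther list, moved apart, by log2 -1.72 on A05 (BnaA05G0051900ZS) and 0.99 on A10 (BnaA10G0260900ZS). PR5 on C03 (BnaC03G0670100ZS) fell by 0.94 ± 0.04 and APL on A08 (BnaA08G0054000ZS) was at 0 in SX3, at least 28.8-fold lower.

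**Figure D2:**
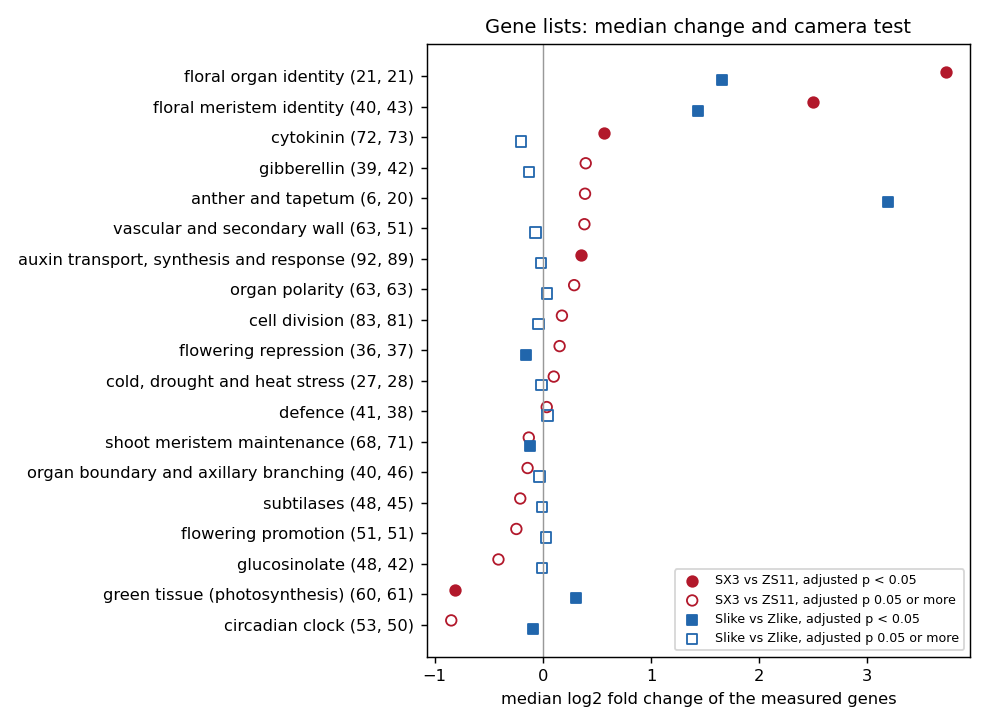
Median log2 fold change of the measured genes of 19 lists, SX3 against ZS11 (circles) and Slike against Zlike (squares), with the numbers of measured genes in brackets and groups at 0 counts at their lower bound; filled symbols have a camera adjusted p under 0.05 at the preset correlation. The floral organ list lies at 3.72 and 1.65 and the floral meristem list at 2.5 and 1.43, while the photosynthesis list lies at -0.82 and 0.31.

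Changed genes were unevenly placed. Of 500 windows of 100 tested genes, 46 held an excess of called genes (Fisher exact test, adjusted over windows), among them 9 on A02 and 6 on C02. In 3 windows between positions 48770 and 6572239 of C02, 100 of 100 genes were called (adjusted p = 1.94e-14). From 0 to 9 Mb of C02, 558 of 619 genes with 1 CPM or more in ZS11 were at least 4-fold lower in SX3, and 277 of them (44.7%) had 0 counts in all 3 SX3 libraries, against 1.70% of such genes elsewhere. Of these C02 genes, 309 had a single A02 copy with the same protein name, and their median log2 change was 0.58 (bootstrap 95% interval 0.49 to 0.76), against -0.41 for the other A02 genes. The summed counts of these pairs had a median log2 ratio of -0.40. Of the named genes, MS1, CYCB1;2, CYCA1;1, LOG8, CKX7, ARF4, PRR7 and the C02 copy of GASA4 lie in this stretch, and FLC and the A02 copies of GASA4 and CKX3 in the range of the A02 copies. In Slike against Zlike 403 of the 619 genes were called lower and 8 higher (median -0.43), and the A02 copies had a median of 0.24. A second stretch, 46 to 48 Mb of C01, had 80 of 85 genes at least 4-fold lower and 29 at 0, and the median change of 49 copies on A01 was 0.94; in Slike against Zlike 72 of the 85 were called lower (median -0.68). The stretches were delimited after the data were seen, and near-identical homoeologs leave counts per copy uncertain.

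**Figure D3:**
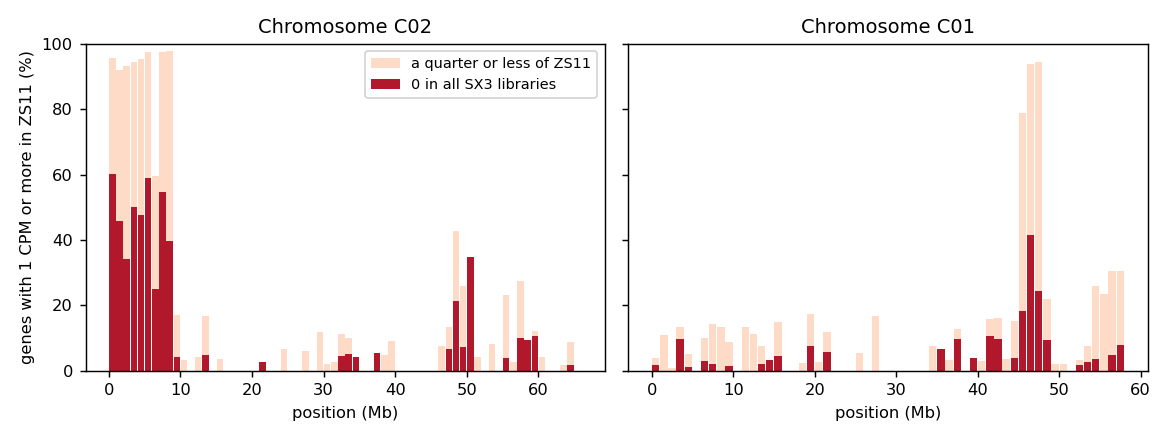
Percent of genes with a mean of 1 CPM or more in ZS11 that were at least 4-fold lower in SX3 (pale bars) or at 0 counts in all 3 SX3 libraries (dark bars), in bins of 1 Mb along C02 and C01; bins with fewer than 10 such genes are not drawn. The bins from 0 to 9 Mb of C02 reach 25% to 60.3% at 0.

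In the authors' deposited table for SX3 and ZS11, 8155 genes carry the word for up and 5301 the word for down. Every gene with the word for up in the authors' deposited table had the lower mean count in SX3, so the words describe ZS11 relative to SX3. Of these genes of the authors' deposited table, 93.0% and 92.4% were called in the same direction by edgeR.

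The second comparison asked which differences recur between backcross plants that resemble one or the other parent. Slike meristems held more transcripts of floral, anther and photosynthesis genes than Zlike meristems. AP3 on A09 (BnaA09G0503200ZS) was at 43.8 ± 0.866 CPM (SD, n = 3) in Slike against 8.21 ± 0.867 in Zlike, and SEP2 on A01 at 24.1 ± 1.57 against 0.858 ± 0.234. SEP2 lies just past the A01 window with the strongest excess of called genes, given below, whose named genes of other functions were also higher in Slike. The anther regulator AMS on C07 (BnaC07G0060300ZS) was at 5.42 ± 0.541 CPM in Slike and at 0 in all Zlike libraries. The edgeR test called 13447 of 49526 genes, 6822 higher and 6625 lower in Slike. Only 2085 differed at least 2-fold, and of these 1783 were higher and 302 lower. With the Wald test of DESeq2 the number called was 8272.

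Floral meristem identity genes were higher in 31 of 43 and lower in 1, with a median of 1.43 (camera adjusted p = 2.31e-31, and adjusted p = 0.00853 with an estimated correlation; over the list alone 32 and 1). SEP2 rose by 4.80 ± 0.16 and SEP1 on C09 (BnaC09G0506000ZS) by 2.46 ± 0.10. Floral organ identity genes were higher in 14 of 21 and lower in 4, with a median of 1.65 (1.73e-19, and adjusted p = 0.0127 with an estimated correlation; over the list alone 15 and 4). AP3 rose by 2.42 ± 0.08 on A09 and by 2.95 ± 0.10 on C08. Anther and tapetum genes were higher in 17 of 20 and lower in 2, over the list alone likewise, with a median of 3.19 when groups at 0 are set at their bound (1.97e-16, and adjusted p = 0.0102 with an estimated correlation). Genes near 0 in Zlike pass the filter only where they are higher in Slike. The counts, median and p-values of this list therefore partly follow from the filter. Without a filter, all 37 list genes summed to 195 ± 5.89 CPM in Slike and 153 ± 3.25 in Zlike. AMS was at least 26.1-fold higher, and DYT1 on A01 (BnaA01G0115100ZS), an early tapetum regulator, was at 5.91 ± 0.825 against 0.046 ± 0.04 CPM. Markers of a later floral tissue thus moved with the group and with the floral lists in Slike. In SX3 they did not: 28 anther genes under 1 CPM in ZS11 and Zlike summed to 3.29 ± 0.772 CPM in SX3 and 44.2 ± 2.72 in Slike.

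Photosynthesis genes were higher in 49 of 61 and lower in 6, over the list alone likewise, with a median of 0.31 (6.66e-30, and adjusted p = 0.0102 with an estimated correlation). CA1 on C05 (BnaC05G0559700ZS), a carbonic anhydrase gene, was at 26.3 ± 1.24 CPM against 0.0911 ± 0.0336, and LHCB1.3 on C03 (BnaC03G0660800ZS) rose 2.88-fold. Flowering repressors were lower in 16 of 37 and higher in 2 (median -0.16, 0.000459, and adjusted p = 0.0417 with an estimated correlation; over the list alone 17 and 2). TOE1, an AP2-type repressor, fell by 0.53 ± 0.06 on A07 (BnaA07G0163100ZS) and 0.59 ± 0.07 on C04 (BnaC04G0195600ZS).

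Shoot meristem maintenance genes were lower in 25 of 71 and higher in 7 (camera adjusted p = 0.0347; over the list alone 25 and 8), and clock genes lower in 12 of 50 and higher in 3 (0.0419). Both calls were lost with an estimated correlation (adjusted p = 0.298 and adjusted p = 0.179). The first was also lost without Zlike replicate 1 (0.0716), and the second without Zlike replicate 3 (0.0813) or Slike replicate 1 (0.064). KNAT6 on A08 (BnaA08G0236500ZS), a meristem homeobox gene, fell by 0.51 ± 0.06 and RPK2 on A01 rose by 1.95 ± 0.16. Of the clock genes, PRR7 on C02 (BnaC02G0007000ZS), between 0 and 9 Mb, fell by 0.83 ± 0.07 and LHY on A10 by 0.34 ± 0.05.

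Among single regulators, AP1 on A07 rose 2.70-fold, from 11.2 ± 0.278 to 30.4 ± 0.704 CPM (edgeR adjusted p = 8.16e-32), FT on C06 rose by 1.54 ± 0.29 (9.06e-06), FUL on A03 by 0.33 ± 0.10 (0.00727, but 0.0568 with DESeq2) and WUS on C09 by 1.63 ± 0.39 (0.00052). TFL1 fell by 0.39 ± 0.05, STM on C09 by 0.25 ± 0.05 and SVP on A09 by 0.29 ± 0.04. FLC on A02 fell by 0.24 ± 0.07 (0.00417), a call lost without Zlike replicate 1 (adjusted p = 0.0589). SOC1 on A03 was at 26.1 ± 2.68 and 25.5 ± 1.24 CPM (adjusted p = 0.819), CLV3 on A04 at 0.768 ± 0.181 and 1.07 ± 0.275 (0.39), and LFY, at 0.259 and 0.0478 CPM, was not tested. SPL5, a promoter of floral transition, rose by 2.36 ± 0.11 on A05 (BnaA05G0401200ZS) and 1.90 ± 0.10 on C05 (BnaC05G0450400ZS). In its list, 11 of 51 promoters were higher and 13 lower (over the list alone 13 and 13). Camera did not call the list (adjusted p = 0.556), while fry did (adjusted p = 0.011).

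The remaining lists were not called by camera, whose adjusted p is given for each list below. Fry called stress (adjusted p = 0.00322), subtilase (0.00546), defence (0.00588) and organ boundary genes (0.011), and none of the others in this paragraph. Cytokinin genes were higher in 12 of 73 and lower in 21 (adjusted p = 0.159; over the list alone 14 and 26), although CKX3, which degrades cytokinin, rose by 3.45 ± 0.30 on A02 (BnaA02G0120800ZS) and 4.18 ± 0.48 on C02 (BnaC02G0149900ZS). Subtilases were higher in 13 of 45 and lower in 14 (0.859; over the list alone 13 and 16), with SBT1.7 on A10 (BnaA10G0088200ZS) higher by log2 0.41 and SBT2.5 on A03 lower by -0.50. Gibberellin genes were higher in 8 of 42 and lower in 8 (0.259; over the list alone 9 and 10), with GASA4 on C02 lower by -0.58 and the DELLA gene RGA on C09 (BnaC09G0254100ZS) by -0.37. Auxin genes were higher in 15 of 89 and lower in 9 (0.735), cell division genes higher in 14 of 81 and lower in 8 (0.859), and organ polarity genes higher in 14 of 63 and lower in 9 (0.859; over the list alone 15 and 11). Their members with the smallest p were MP on C08 (BnaC08G0256200ZS), higher by 0.33, GH3.6 on C02 (BnaC02G0166500ZS), lower by -0.44, MCM7, higher by 0.32 on C03 (BnaC03G0328000ZS) and lower by -0.32 on A03 (BnaA03G0272900ZS), AS1 on C04 (BnaC04G0090000ZS), lower by -0.37, and REV on A10 (BnaA10G0159600ZS), lower by -1.12. Glucosinolate genes were higher in 9 of 42 and lower in 13 (0.854; over the list alone 9 and 14), with SUR1 on A03 (BnaA03G0504500ZS) at 20.8 ± 0.769 against 0.535 ± 0.33 CPM and CYP83A1 on A04 (BnaA04G0074700ZS) higher by 1.29. Organ boundary and branching genes were higher in 10 of 46 and lower in 6 (0.735); copies of RAX3, an axillary meristem regulator, were at 1.65 ± 0.437 against 0.0244 CPM on A01 (BnaA01G0012300ZS) and 1.43 ± 0.201 against 0.0216 on A09 (BnaA09G0092700ZS). Stress genes were higher in 5 of 28 and lower in 4 (0.183; over the list alone 6 and 4), defence genes higher in 10 of 38 and lower in 4 (0.735; over the list alone 11 and 5), and vascular genes higher in 6 of 51 and lower in 12 (0.556). RD22, a dehydration-response gene, rose by 1.31 on A02 (BnaA02G0379600ZS) and 1.22 on C02 (BnaC02G0508100ZS), WRKY70 on A09 (BnaA09G0519800ZS) by 0.82, while PR5 on C03 was lower by -0.32, APL on C06 by -0.56 and SEOR1 on C01 (BnaC01G0493500ZS) by -0.84. Median and mean differed in sign for cytokinin, auxin, stress, glucosinolate, organ boundary, subtilase and vascular genes.

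The genes with the smallest p that were at least 2-fold higher in Slike were HIS2B on A10 (201 ± 6.64 against 5.30 ± 1.59 CPM), GDSL lipase genes with best match At5g33370 on C08 (BnaC08G0114000ZS, 141 ± 7.87 against 7.11 ± 0.734) and A08 (BnaA08G0080500ZS, 125 ± 6.52 against 6.34 ± 1.09), the cell wall protein gene At2g20870 on C08 (BnaC08G0457100ZS), higher by log2 4.18, and MLP423 on C07 (BnaC07G0170500ZS), 5.57-fold higher. The 5 lower genes all lay on A10. They were nep1 (BnaA10G0258600ZS), an aspartic protease gene lower by -1.2, AGP15 (BnaA10G0233200ZS) by -1.48, LIP (BnaA10G0062000ZS) by -1.32, the mitochondrial ATP synthase gene At5g08680 (BnaA10G0251400ZS) by -1.21 and YLS9 (BnaA10G0232200ZS) by -1.47.

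Called genes of Slike against Zlike clustered on a few chromosomes. Of 493 windows, 41 held an excess, 11 of them on A10, 6 on C01, 6 on C02, 5 on A02 and 4 on A01. With calls limited to 2-fold changes 18 windows did. The strongest, A01 35572316 to 36962946, had 96 of 100 genes called (adjusted p = 1.96e-46) and 88 of 100 at 2-fold or more. Its genes with the smallest p were GAPC (BnaA01G0404200ZS, log2 1.5 ± 0.04), RPS3A (1.54 ± 0.05), RPS7 (BnaA01G0414600ZS, 1.87 ± 0.06), the copper chaperone gene ATX1 (BnaA01G0399200ZS, 1.97 ± 0.07) and HDA19 (BnaA01G0402200ZS, 1.35 ± 0.05), a histone deacetylase gene; all were higher in Slike. By chromosome, 44.4% of tested A10 genes were called (odds ratio 2.21, two-sided Fisher exact test across genes, adjusted p = 1.11e-55), and 11.6% of A10 genes and 11.0% of A01 genes differed at least 2-fold (odds ratios 3.22 and 3.09).

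**Figure D4:**
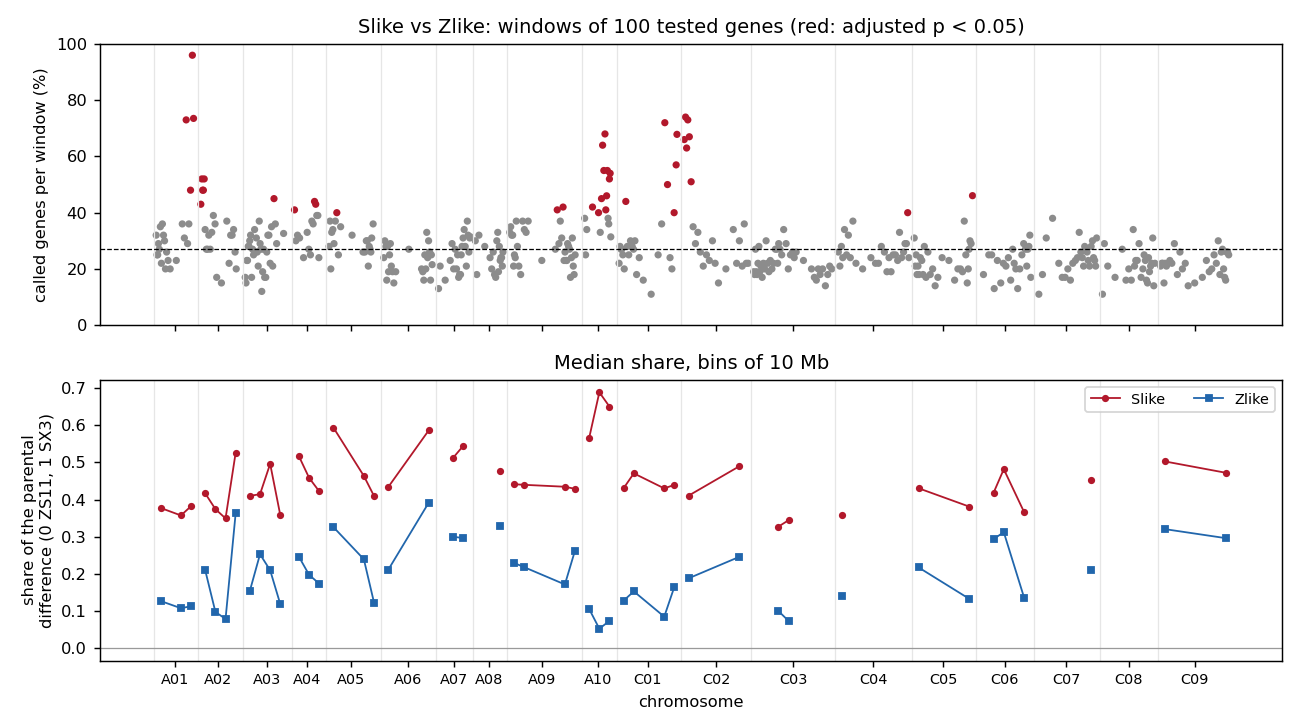
Upper panel, percent of called genes in Slike against Zlike per window of 100 tested genes along the 19 chromosomes, with the mean over all genes (27.2%) as a dashed line. Lower panel, median share of the parental difference per 10 Mb bin with at least 20 genes, on a scale where 0 is the ZS11 level and 1 the SX3 level; on A10 the Slike median is 0.651 and the Zlike median 0.0634.

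In the authors' deposited table for Slike and Zlike, 168 genes carry the word for up and 1672 the word for down, again describing the wild-type class relative to the mutant class. Of these genes of the authors' deposited table, 97.6% and 89.5% were called in the same direction by edgeR.

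The comparisons overlapped, and they share no library. Of 48315 genes tested in both, 4394 were higher in both mutant types, against 2131.66 for independent lists, and 5156 were lower in both, against 2377.43; 1598 were called in opposite directions. With 2-fold changes, 1020 genes were higher in both (133 for independent lists) and 198 lower in both (39.8; Fisher exact test across genes, p = 1.05e-107). Fold changes correlated across genes (Pearson r 0.517, Spearman rho 0.491), and genes are not independent replicates. HIS2B, RPS2A, At2g20870 and both At5g33370 copies led the genes higher in both. In Slike against Zlike, RPS2A on C03 was at 93.8 ± 2.17 against 9.81 ± 0.725 CPM. Those lower in both were nep1, AGP15, LIP, the histone H1 gene At2g30620 on A10 (BnaA10G0047900ZS), by -1.27 in SX3 and -0.74 in Slike, and At3g49630 on A01 (BnaA01G0217200ZS), by -3.70 and -0.66. Across the genome, 2687 genes differed at least 4-fold between the parents at 5 CPM or more. On the scale from ZS11 to SX3 their median lay at 0.175 in Zlike and 0.432 in Slike. Of the 2687 genes, 418 lay at 0 to 10 Mb of C02, 160 at 30 to 40 Mb of A01 and 88 at 40 to 50 Mb of C01. The medians lean on these stretches to that extent, and none was computed without them.

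The contrast of both comparisons asked whether the mutant type differed from the wild type by the same fold in the parents and in the backcross. It differed for 27515 of 51650 genes (edgeR, all 12 libraries), 15533 with a positive contrast and 11982 with a negative one. For photosynthesis genes the contrast was positive in 53 of 62 and negative in 5 (camera adjusted p = 1.03e-26, and adjusted p = 0.000158 with an estimated correlation): the list fell in SX3 and rose in Slike. For floral meristem identity it was negative in 21 of 43 and positive in 3 (0.00658; over the list alone 23 and 3; adjusted p = 0.0633 with an estimated correlation), the fold change in SX3 being larger. FLC on A02 had a contrast of 3.32 and AP1 on A07 one of -1.74.

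Backcross plants also differed from the parent of the same type. In these comparisons a difference in growth, harvest or stage between parents and backcross plants cannot be told apart from genetic background. The same limit holds for the scale from ZS11 to SX3 on which Zlike and Slike were placed. Zlike against ZS11 gave 23736 called genes of 51650 (11928 higher, 11808 lower, 4931 at least 2-fold), and Slike against SX3 gave 27714 (15369 higher, 12345 lower, 8930 at least 2-fold). SOC1 on A03, a promoter of flowering, was at 93.4 ± 4.14 CPM in ZS11 and 86.5 ± 1.28 in SX3 but at 25 ± 1.2 in Zlike and 25.6 ± 2.64 in Slike, a log2 change of -1.90 ± 0.05 in Zlike against ZS11 (edgeR adjusted p = 1.83e-65) and -1.76 ± 0.05 in Slike against SX3 (3.78e-61). AP1 on A07 was higher in Zlike than in ZS11 by 2.23 ± 0.14 and in Slike than in SX3 by 0.49 ± 0.08. STM on C09 was lower in both, by log2 -0.82 and -0.52. FT on C06 was lower in Slike than in SX3 by log2 -1.87, while Zlike and ZS11 were at 0.854 ± 0.204 and 0.697 ± 0.273 CPM (adjusted p = 0.539). FLC on A02 was higher in Slike than in SX3 by 3.02 ± 0.11.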

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

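All tests of explanations in this part were chosen after the results they bear on had been seen, and the limits of 2-fold and of 3 counts used below were set after the number of differing genes was known; the contrast itself and the counts of other splits were planned beforehand. The contrast (Slike − Zlike) − (SX3 − ZS11), tested with edgeR on all 12 libraries, differed from 0 by at least 2-fold for 56 of 101 named genes, after leaving out 22 with a group at 3 counts or fewer. It was positive for 36 of the 56. Over all tested genes the contrast was called at 2-fold or more for 11656 of 51650, with 66.1% of these positive. Most named genes were chosen by small p in the comparisons that form the contrast. Their count therefore partly follows from that choice and shows nothing particular to them. Values below are this contrast on the log2 scale. A positive value means that the change was more positive in the backcross plants than between the parents.

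Among floral and flowering genes the contrast was negative, with the fold change larger between the parents, for SEP1 (C03 -3.20, C09 -3.77), PI on C03 (-2.76), AP3 (A09 -1.89, C08 -2.61), AP1 on A07 (-1.74), FT on C06 (-2.16) and SVP on A04 (-2.31), and negative for TOE1 (A07 -1.09, C04 -1.79) and FIL on C04 (-1.08). A larger fold need not be a larger rise in level. AP3 on C08 went from 0.254 to 12.3 CPM between the parents and from 4.46 to 34.7 CPM in the backcross. The contrast was positive for FLC on A02 (3.32), SPL5 on C05 (1.64), AGL24 on C01 (1.32) and REV on A10 (1.43). Clock, light-harvesting and heat shock genes gave 7.37 and 6.56 for LHY on A10 and C05, 4.16 for LHCB1.1 on A03, 2.99 and 1.24 for LHCB1.3 on A04 and C03, and 3.02 and 3.70 for HSP101 on A07 and C06. Hormone and branching genes gave -1.87 and 7.12 for GASA4 on A02 and C02, 6.20 for LOG8 on C02, -3.10 for GH3.6 on A03, 1.60 for PIN3 on A07 and 1.95 for D14 on C05. Subtilase and glucosinolate genes gave 4.09 for SBT3.3 and 1.83 for SBT2.5 on A03, 2.33 for SUR1 on A03, 2.76 for CYP83A1 on A04, and 2.33 and 2.54 for MYB34 on C06 and C07. Genes of the A01 window gave -3.16 for ATX1, -4.52 for RPS3A, -2.86 for HDA19, -2.61 for GAPC and -8.22 for RPS7. On A10 the values were 2.04 for LIP, 2.00 for YLS9, 2.53 for AGP15, 1.34 for At5g08680 and 1.2 for nep1. The others were 10.12 for the methionine synthase gene MS1 on C02, 5.10 for TIP1-1 on A04, 3.62 for PER22 on C03, 3.04 for At3g49630 on A01, 2.24 for MCM7 on A03, 2.07 for SEOR1 on C01, 1.67 for MLP423 on C07, 1.36 for EMS1 on A05, 1.28 for APL on C06, 1.21 for RD22 on A02, -2.48 for ATL5 on C07 and -4.03 for At2g20870 on C08. LOG8, MS1 and the C02 copy of GASA4 lie between 0 and 9 Mb of C02.

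For 9 lists camera gave an adjusted p of the contrast under 0.05: photosynthesis (1.03e-26), cytokinin (0.00185), anther and tapetum (0.00343), floral meristem identity (0.00658), floral organ identity (0.00878), auxin (0.00878), subtilases (0.00878), glucosinolate (0.0289) and gibberellin (0.0308). With an estimated correlation the adjusted p was 0.000158 for photosynthesis and 0.041 for cytokinin, auxin and subtilases; for the others it was 0.07, 0.0633, 0.07, 0.0611 and 0.158, for anther, floral meristem, floral organ, glucosinolate and gibberellin genes in this order. Median and mean of the contrast had the same sign in these 9 lists. The anther list had 20 measured genes here but 6 in SX3 against ZS11. Most of its genes thus passed the filter through the backcross libraries, and its p-value partly follows from that.

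Floral genes were higher in both mutant types, which could reflect apices that held more or older flower buds. Buds that already bore anther tissue in the Slike samples go with the 37 anther and tapetum genes, which summed to 195 ± 5.89 CPM in Slike and 153 ± 3.25 in Zlike. The list median of 3.19 in Slike against Zlike partly follows from the filter, which kept genes near 0 in Zlike only where Slike was higher. The list argues against as much anther tissue in SX3: 28 anther genes under 1 CPM in ZS11 and Zlike summed to 44.2 ± 2.72 CPM in Slike and 3.29 ± 0.772 in SX3, which is 7.43% of the Slike level. The floral lists rose more in SX3 as fold changes, but in level AP1 on A07 lay at 21.3 CPM in SX3 and 29.8 in Slike. The anther genes therefore do not exclude fewer or younger buds in SX3. Over all 37 list genes, the measure tried first, SX3 reached 60.8% of Slike, which decided nothing because ZS11 already held 151 ± 1.29 CPM. A scaling error shifts all genes of a comparison alike, and is argued against by the floral meristem list, whose median lay at least 1.43 above that of all tested genes in both comparisons (bootstrap 95% interval 0.832 to 1.63 in Slike against Zlike). This gap restates the camera call of the list, which already set it against all other genes, and is no separate test. DESeq2 size factors, tried first (camera adjusted p = 6.14e-09), hardly moved the values and decided nothing. Fewer buds or an earlier flower stage without anthers in SX3, and a direct effect of the mutation on floral genes, stay open and were not tested.

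Slike lay closer to SX3 than Zlike did for genes that differ between the parents, which could come from inherited SX3 segments, from SX3 RNA mixed into Slike, or from a developmental shift shared by both mutant types. A mixture of SX3 RNA with RNA of the Zlike type, as the whole cause, is argued against by A10, where the Slike share exceeded that on the other chromosomes by 0.225 (bootstrap 95% interval 0.199 to 0.271) although the Zlike share was lower there (0.0634 against 0.179), and by neighbouring genes outside A10, which resembled each other in the share of SX3 RNA that a mixture would need (rank correlation 0.125, permutation p = 0.0001, the smallest that 10000 shuffles can give). A shared shift as the whole cause, which acts on genes wherever they lie, is argued against by Slike share minus Zlike share, which on A10 exceeded that on the other chromosomes by 0.285 (0.225 to 0.318), against at most 0.0958 for any chromosome in 10000 shuffles. Slike share minus Zlike share was nevertheless above 0 on every chromosome, from 0.153 on C09 to 0.588 on A10. A shared shift or a mixture as part of the cause therefore stays open. Inherited segments go with the resemblance of neighbouring genes in Slike share minus Zlike share (rank correlation 0.142, permutation p = 0.0001), a hypothesis found and tested on the same data, and coexpressed neighbours would add to it. The stretches of C02, A01 and C01 that hold many of these genes were kept in all tests of neighbours, and no value without them was computed. Measures tried first decided nothing: of 140 genes seen in SX3 alone, 140 had counts in Slike and 136 in Zlike, a gap of 2.86 points, with 0% at 0 in Slike; genes seen in ZS11 alone fell in Slike (median -0.53, 357 of 419 called lower), as a shared shift would also give; and neighbours outside A10 resembled each other in Slike share (0.109), as a mixture would also give where Zlike shares vary along chromosomes.

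Transcripts along a stretch of C02 and a stretch of C01 were mostly lower in SX3, 44.7% and 34.1% of them at 0, while their A-subgenome copies rose, a pattern that may come from exchange between homoeologous segments, a loss of the C02 segment, or low expression. Low expression by a developmental change that acts on both copies of a gene is argued against, narrowly by the limit set, by the A-subgenome copies of 77 lower genes of the C02 stretch, whose median change lay 0.52 (bootstrap 95% interval 0.25 to 0.86) above that of the copies of 121 C-subgenome genes that fell at least 4-fold elsewhere (0.39 against -0.13); the share at 0 within the C02 stretch and the run of 9 bins of 1 Mb with 20% or more of genes at 0, tried first, decided nothing because the stretch was delimited by them (18% at 0 over 0 to 51 Mb). A loss of the C02 segment that leaves the A02 counts unchanged is argued against by the median change of 0.58 in the A02 copies. That rise does not show extra A02 copies, so a loss with a rise of A02 counts for another reason stays open. Exchange stays open: the A02 copies lay 0.99 above the other A02 genes, where extra A02 copies would place them, and the summed counts of the pairs had a median log2 ratio of -0.40, further from 0 than the limit set for a balanced exchange but no lower than the other A02 genes (-0.41), and of -0.10 for C01 and A01, within that limit. Silencing of the C02 segment alone, and reads assigned to the A02 copy because the SX3 sequence lies closer to it, were not tested apart, and in Slike against Zlike the C02 genes moved the same way (403 of 619 called lower, 8 higher, median -0.43) with 1 of them at 0 in Slike and 1 in Zlike.

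Other groupings of the libraries were fitted in the same way. For SX3 against ZS11 (34681 genes), Slike against Zlike (13447), Zlike against ZS11 (23736) and Slike against SX3 (27714), 1 of 10 splits of the 6 libraries, the real one, gave as many called genes and the highest other gave 0; 10 splits are too few for a share under 0.05. For the contrast (27515 genes), 1 of 100 combinations of splits within the parents and within the backcross, the real one, gave as many called genes, and the highest other gave 26554. That share rests on 90 combinations that regrouped the parents, where the difference between the parents enters the spread and leaves few calls by construction (0 to 61 genes). The 9 others that kept the parents as labelled gave 24181 to 26554, and 10 combinations are too few for a share under 0.05.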

How the results depend on the processing

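All alternatives reported here were planned before the data were examined. The number of called genes stayed within 1.5 times the main number for SX3 against ZS11 (30538 with DESeq2 to 37647 without a filter, against 34681), the contrast (24099 with DESeq2 to 27928 without a filter, against 27515), Zlike against ZS11 (19476 to 23736) and Slike against SX3 (24225 to 27714). For Slike against Zlike DESeq2 called 8272 genes against 13447, all 8272 among the 13447 and in the same direction; the overlap in the same direction then fell from 9550 to 6026 genes. The cause was not tested. Limited to 2-fold changes the overlap was 1218 genes, and the number of windows fell from 41 to 18 for Slike against Zlike but rose from 46 to 69 for SX3 against ZS11; the cause was not tested. With an estimated correlation 2 of 5 called lists remained for SX3 against ZS11, and 5 of the list results over both comparisons lost their call. Leaving out 1 library gave 33293 to 33907 genes for SX3 against ZS11, 11277 to 11905 for Slike against Zlike, 26470 to 26785 for the contrast, 8071 to 9464 in the overlap, 5 called lists for SX3 and 6 to 7 for Slike, and 44 to 52 and 35 to 43 windows. At least 79.1% of the calls of Slike against Zlike were kept.

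Of 130 results for named genes, 1815 values under alternatives kept direction and side of the threshold in 1803 cases. CLV3 on A04, not called in SX3 against ZS11 (-0.02, and -0.271 to 0.222 with 1 library left out), changed sign with upper-quartile scaling (0.034), without ZS11 replicate 1 (0.08) or 3 (0.14) and without SX3 replicate 2 (0.22). SOC1 on A03, not called in Slike against Zlike (0.03, and -0.045 to 0.106 with 1 library left out), changed sign without Zlike replicate 3 (-0.001) and Slike replicate 2 (-0.045). The 6 calls lost or gained are given with the genes. In all of these cases the cause was not tested.

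Replicate numbers do not pair the samples: over 18 same-numbered pairs, deviations from the group means correlated between -0.03 and 0.02. With the replicate number as a block, 34412 genes were called for SX3 against ZS11, 13300 for Slike against Zlike, 27396 for the contrast and 9445 in the overlap, and no call of a list or named gene changed in SX3 against ZS11 or Slike against Zlike; lists and named genes of the contrast were not run with it. No scaling moved the median of all genes by over 0.1; upper-quartile scaling moved it to 0.05 in SX3. Depth limits genes such as the one matched to LFY, whose levels (0 to 0.259 CPM) lie near the floor of 0.169 to 0.223 CPM for a library at 0. LFY copies under another protein name would not be covered by this gene.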

Other observations

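Protein families were tested only after the data had been seen. Of 452 Pfam families with at least 20 measured genes, the chlorophyll a-b binding proteins had the smallest p in SX3 against ZS11, with 63 of 79 genes lower and 11 higher (median log2 -1.07, camera adjusted p = 4.54e-11). Core histone genes were higher in 76 of 106 and lower in 20 (median log2 0.67, camera adjusted p = 6.46e-09), genes of the ribosomal L7Ae family higher in 38 of 46 (0.81, 4.70e-09), and genes of the L15, L18e and L27A family higher in 23 of 24 (0.89, 6.40e-10). NF-YA genes, subunits of a CCAAT-binding factor, were lower in 26 of 30 and higher in 1 (-1.24, 0.000444), major intrinsic proteins (aquaporins) lower in 51 of 74 (-0.59, 0.000672) and universal stress proteins lower in 41 of 66 (-0.38, 0.00381). With an estimated correlation none of the 25 families with the smallest p passed in either comparison (adjusted p of at least 0.206 in SX3 against ZS11 and at least 0.164 in Slike against Zlike).

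The DUF640 family, which holds the ALOG regulators of meristem and inflorescence form, was lower in both mutant types: 22 of 33 genes were lower and 5 higher in SX3 (median -0.92, camera adjusted p = 0.00377), and 18 lower and 2 higher in Slike (-0.37, 4.14e-07); with an estimated correlation the adjusted p = 0.24 and 0.206. In Slike against Zlike the MADS-box domain family was higher in 16 of 29 (0.84, 1.52e-09), cupins in 14 of 24 (1.02, 2.52e-13), lipid transfer and seed storage proteins in 14 of 22 (0.56, 8.04e-13), GDSL lipases in 50 of 121 with 17 lower (0.24, 1.73e-08) and SBP-domain genes in 22 of 57 with 5 lower (0.11, 5.12e-05). Each of these calls was lost with an estimated correlation (camera adjusted p of at least 0.164). Response regulators went up in SX3 (26 of 42 higher, 6 lower, 0.80) and down in Slike (17 of 40 lower, 4 higher, -0.22), with adjusted p of 0.00128 and 0.0225; with an estimated correlation both calls were lost (adjusted p = 0.237 and 0.511).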
